A study of Mus musculus with 6 samples.

How the data were processed

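Aortic arch and thoracic aorta RNA from 6 mouse samples, 3 Apoe-/- controls and 3 Apoe-/- Mir26b-/- knockouts after 4 weeks of high-fat diet, had been sequenced, and groups and replicate numbers were taken from the sample labels. Per the submitters' processing notes, FastQC 0.11.8, Trim Galore 0.6.5 and kallisto 0.46.2 were used with GRCm38; kallisto assigns reads to transcripts without a genome alignment and shares a read between similar transcripts. Per the labels, RNA was extracted with a column kit and had a mean integrity of 7.0.

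The deposited estimated counts of 36557 gene rows are not whole numbers. Within each library the value of 1 read was a constant between 0.9004 and 1.0685, with a geometric mean of 1.0 over the libraries, which is what division by a size factor per library would give; no label used here records that step; with these constants undone, 69.2% to 70.9% of low values were whole within 0.02. The second deposited table holds TPM values that were rescaled by the authors and is used as a signal, since its columns sum to between 955527 and 1034723. Of the rows, 10671 were 0 in all libraries, 566 had an ID outside the reference annotation (mostly copies on alternative scaffolds) and 446 symbols had more than 1 ID. Reads of such copies are split, which can put 1 gene into a count of calls more than once. The labels do not say whether the libraries keep strand, so overlapping and antisense genes cannot be separated.

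The estimated counts were rounded to whole numbers, filtered with filterByExpr (minimum count 10), scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F-test) in R 4.3.3; calls have a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold divided by the root of F. The biological coefficient of variation was 0.164. Gene lists (45 fixed before the data were examined, 43 with at least 4 tested members and used as a test) were compared with the other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists, and also with an estimated correlation and with fry. Seed sites were searched in the longest 3′ UTR of protein-coding transcripts in GENCODE mouse release 21, which also gave coordinates, all on GRCm38. The 359 shuffled sequences hold no CG.

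Genes were named by a rule fixed before the data were examined. It took the targeted and host genes, the 10 largest called changes each way with a mean log2 CPM of at least 0, no overlap of groups and no predicted or clone name, up to 4 members of lowest p in each called list and 3 in other lists, and any literature target that passed. In the report this rule's list members are given as examples, and genes of families are marked where reads may be split.

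The fit was also run on 10 sets of simulated counts made from these libraries' means and sizes. Each had 200 changed genes among about 17226, drawn from genes with a mean of at least 1 CPM. The fit recovered 35.7% of 1.5-fold, 75.7% of 2-fold and 97.3% of 4-fold changes, which does not cover genes of lower level. Of all calls, 7.1% were unchanged genes, above the nominal 5% (0.05). The first set alone gave 9.3%, and the number of sets was raised from 1 to 10 after that was seen, with the first included. Genes varied independently in these sets and no library was placed between the groups, so these rates need not hold for the real libraries. Camera called 0 lists in unchanged simulated data, but genes vary independently there, so this does not measure its false calls in these libraries. No pair of libraries in a group agreed within sampling noise; the mean chi-square per gene was between 11.76 and 106.81. Deposited totals were between 51634139 and 54817547 counts per library, and this depth limits the precision of genes near 0 CPM.

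Alternatives were other scaling (median of ratios, upper quartile, library size alone), no or stricter low-count filters (mean count 10 and mean log2 CPM 1), DESeq2 1.42.0, limma-voom with and without sample weights, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, a perivascular fat covariate, omission of X and Y genes or of genes of neighbouring tissues, omission of each library in turn, and other definitions of the seed site. Removal of the scaling constant and summing of copies were chosen after seeing the data.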

Results

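RNA was measured by sequencing in the aortic arch and thoracic aorta of 6 Apoe-/- mouse samples after 4 weeks of a high-fat diet. Mice lacking apolipoprotein E clear cholesterol-rich lipoproteins poorly and develop atherosclerotic plaque on such a diet. The control group held 3 Apoe-/- libraries and the knockout group held 3 libraries from Apoe-/- animals that also lacked the microRNA gene Mir26b. The deposited estimated counts summed to between 51634139 and 54817547 per library. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries. Levels are given in CPM, counts scaled to the library total, after TMM scaling, as mean ± SD with n = 3 per group.

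The comparison asked how loss of Mir26b changes gene expression in the atherosclerotic vessel. Mir26b (ENSMUSG00000065468) lies on chromosome 1 from 74394310 to 74394394 on the plus strand (GRCm38), in the intron between exons 4 and 5 of the 7 exons of the transcript Ctdsp1-201, and its mature form UUCAAGUAAUUCAGGAUAGGU pairs with the 8-base site UACUUGAA in 3′ UTRs. The count table had 0 rows for microRNA genes, so the deletion itself was not checked here. The host gene Ctdsp1 (ENSMUSG00000026176, chromosome 1, 74391509 to 74397285), a phosphatase gene, stood at 195 ± 3.65 CPM in controls and 188 ± 6.84 CPM in knockouts, with an edgeR adjusted p of 0.555. Ctdsp2 and Ctdspl, hosts of the related miR-26a genes, had log2 differences of -0.02 (SE 0.06) and -0.24 (SE 0.08), with adjusted p of 0.834 and 0.0945. Reads assigned to Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188) were present in both groups at 27.9 ± 1.90 and 41.9 ± 3.27 CPM, higher in the knockouts by 0.58 on the log2 scale (SE 0.08) with an adjusted p of 0.0213. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d had low and like levels in both groups, with adjusted p between 0.834 and 0.912. Their means were between 0.635 CPM (Ddx3y) and 2.93 CPM (Kdm5d) in controls and between 0.666 CPM (Eif2s3y) and 2.99 CPM (Kdm5d) in knockouts. Xist, the other gene fixed for this check, was not among the tested genes, so the sex of the animals was not settled.

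Aortas of the knockout group carried far higher levels of inflammatory and plaque macrophage genes, higher interferon-induced genes and lower smooth muscle contractile genes. Spp1, which encodes osteopontin, rose 22.7-fold from 74.6 ± 71.4 to 1695 ± 1177 CPM, Cd5l, a macrophage survival factor, rose 18.3-fold from 17.1 ± 1.77 to 313 ± 254 CPM, and the cytokine genes Il6 and Il1b rose 29.4-fold and 14.6-fold. The folds were 50.6 for Spp1 without control replicate 1, 44.9 for Il6 without control replicate 2 and 11.9 for Cd5l without knockout replicate 2, with edgeR adjusted p of 0.112, 0.0873 and 0.116. The transcriptional coactivator of smooth muscle genes, Myocd, fell from 72.8 ± 4.83 to 25.8 ± 4.39 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1131 of 17392 tested genes were higher and 667 were lower in the knockouts. Of the higher genes, 599 differed by at least 2-fold, against 48 of the lower genes. Groups did not overlap for any of the 1798 called genes, which the call itself favours and which is no separate support. They did not overlap for 36.1% of all tested genes, where chance gives 10% for each gene. Genes that move together over the libraries can raise this share together, so it does not test the genotype.

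The count rested on the composition of the 6 libraries. Knockout replicate 3 lay between the groups on the first principal component (61.9% of variance), at 0.97, where the controls ranged from -45.35 to -25.42 and the other knockouts stood at 47.05 and 55.72. Without this library edgeR called 3051 higher and 2028 lower genes, and these took in 1796 of the 1798. Without control replicate 1 or control replicate 3 it called 0 genes, with 4056 genes at an unadjusted p under 0.05 in each case. The lowest edgeR adjusted p were then 0.0576 and 0.0524, just over the threshold, and leaving out any library also leaves fewer residual degrees of freedom. DESeq2 called 1482 higher and 856 lower genes without the former and 1445 and 771 without the latter, and limma-voom called 0 in both cases. Without control replicate 2, knockout replicate 1 or knockout replicate 2, edgeR called 52 and 19, 7 and 5, and 40 and 22 genes. With library size alone as the scaling, the calls were 1476 higher and 447 lower, so that 76.8% were higher, against 62.9% in the TMM-scaled fit. With the perivascular fat level as a covariate, 147 genes were higher and 135 lower.

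**Figure D1:**
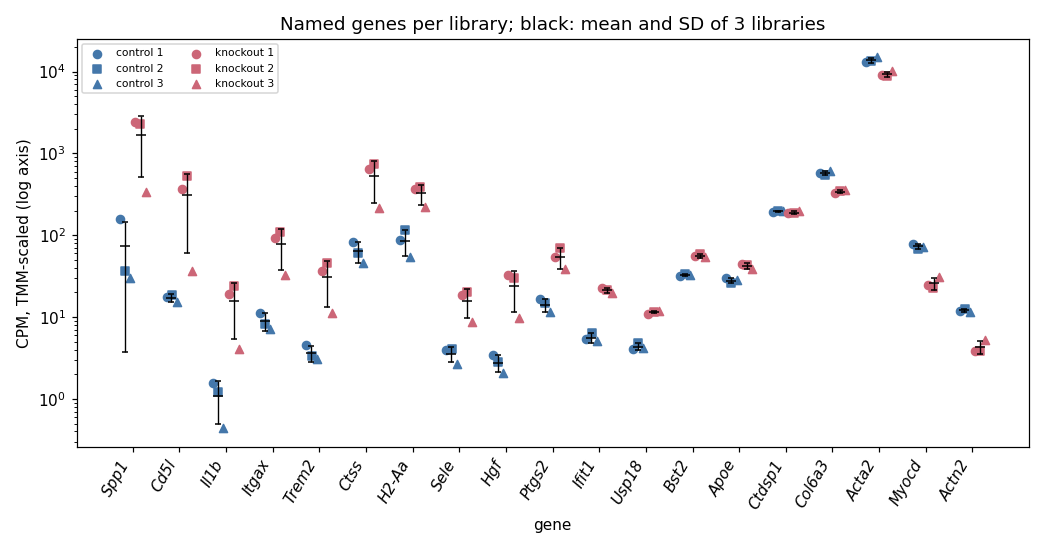
CPM on a log axis for 19 named genes in each of the 6 libraries, with blue points for controls, red points for knockouts and black bars for the mean and SD of 3 libraries. Knockout replicate 3 (red triangles) sits between the controls and the other knockouts for Spp1 at 338 CPM, and beside the other knockouts for Ifit1 at 19.8 CPM and Myocd at 30.8 CPM.

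The largest changes are given here for genes with a mean log2 CPM of at least 0, leaving out predicted and clone names, some of which changed more. Further genes among those with the largest rise were Clca3a2, 27.2-fold (0.931 ± 0.697 against 25.4 ± 13.5 CPM), the lysosomal channel gene Mcoln3, 18.3-fold, Zfp264, 16.1-fold, Ugt1a6b, 13.5-fold, and Fam83f, 12.3-fold. The chemokine gene Ccl21b had 0 counts in all 3 controls and 2.78 ± 2.92 CPM in the knockouts, at least 48.2-fold higher when the controls are set to the floor of 3 counts per library; without knockout replicate 2, which held 6.11 CPM, the limit was 19.3-fold. Its reads can be shared with near-identical Ccl21 copies. The largest falls were of Gal3st2 (3.19 ± 2.08 to 0.0632 ± 0.0788 CPM), the sialidase gene Neu2 (7.46-fold lower), Mmd2 (4.03-fold lower), the cartilage matrix gene Cilp2 (3.72-fold lower) and, after Myocd at 2.82-fold, the actinin gene Actn2 (2.80-fold lower). Tent5b, Pi15, Lgi3 and Dgkg were 2.73-fold, 2.62-fold, 2.58-fold and 2.49-fold lower. Clca3a2, Ugt1a6b and Dgkg had adjusted p of 0.0235, 0.0062 and 0.0078, with log2 standard errors of 0.69, 0.23 and 0.10. The fold was 46.4 for Clca3a2 without control replicate 1, 28.8 for Zfp264 without control replicate 2, and for Gal3st2 (48.8 in all libraries) 30.7 without control replicate 3 and 150 without knockout replicate 3. Ugt1a6b and Gal3st2 are members of families with similar genes on chromosome 1, so their split of reads is uncertain. Both lie within 20 Mb of Mir26b, as do Neu2 and the collagen gene Col6a3 named below. Whether genome carried with the knockout allele has a part in the changes of these genes was not tested gene by gene.

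Macrophage genes were higher. In the macrophage list, 17 of 22 tested members rose and 1 fell (adjusted over the list alone, 19 and 2), with Ctss, a lysosomal protease gene, rising 8.40-fold to 533 ± 282 CPM, the Fc receptor gene Fcgr1 5.57-fold, the chemokine receptor gene Cx3cr1 3.88-fold and Ms4a7 6.59-fold. In the foam cell and lipid-laden macrophage list, 16 of 21 members rose and 0 fell (17 and 0 over the list alone); the integrin gene Itgax rose 8.73-fold, the elastase gene Mmp12 11.4-fold, the lipid receptor gene Trem2 8.47-fold and the cholesterol exporter gene Abcg1 4.90-fold. Trem2 has a second row with the same values, so its reads were split over 2 copies. The scavenger receptor list had 5 of 15 members higher and 0 lower (9 and 1 over the list alone), Cd68 among them at 6.02-fold, and the list of cholesterol efflux and LXR targets had 7 of 18 higher (12 over the list alone), with the phospholipid transfer gene Pltp at 2.76-fold. Camera with a preset correlation called all 4 lists, with adjusted p of 2.75e-12, 2.75e-12, 0.000172 and 2.13e-06, and with an estimated correlation each had an adjusted p = 0.422. The lists overlap. Knockout replicate 3 had a median log2 rise of 0.89 in the macrophage list, where the other knockouts had 2.03 and 2.18.

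Inflammatory mediators rose with them. Of 34 tested cytokines and chemokines, 21 rose and 0 fell (29 and 0 over the list alone), with the prostaglandin synthase gene Ptgs2 3.83-fold, the chemokine genes Cxcl14 9.05-fold, Cxcl16 3.54-fold and Ccl11 1.44-fold higher. For leukocyte adhesion 8 of 19 rose and 2 fell (11 and 2 over the list alone); the endothelial adhesion gene Sele rose 4.48-fold and the integrin gene Itgb2 4.81-fold. For complement 13 of 17 rose and 0 fell (14 and 0), C1qb by 3.98-fold. Of 10 MHC class II genes 6 rose (7 over the list alone), H2-Aa from 86.1 ± 30.5 to 324 ± 91.0 CPM. Of 13 neutrophil genes 1 rose (3), the receptor gene Csf3r at 4.71-fold. Of 33 matrix proteases and inhibitors 15 rose and 0 fell (20 and 1), Mmp13 by 6.87-fold. Camera called these 6 lists, at adjusted p of 1.95e-15, 0.00199, 6.42e-10, 3.6e-06, 0.00346 and 1.58e-06, and with an estimated correlation their adjusted p were 0.422, 0.422, 0.422, 0.448, 0.609 and 0.422. Of 22 T cell genes 1 rose, the cytokine receptor gene Il7r at 6.78-fold, and the list had an adjusted p of 0.0502, which was 0.0198, 0.00346 and 0.0449 without control replicate 1, control replicate 2 and knockout replicate 1, and 0.734 with an estimated correlation in all 6 libraries. Knockout replicate 3 stood below the other knockouts in these lists, with a median log2 level over the control mean of 0.81 for cytokines and chemokines (2.14 and 2.25 in knockout replicates 1 and 2), 0.21 for leukocyte adhesion (0.71 and 0.70), 0.58 for complement (1.28 and 1.39), 0.89 for MHC class II (1.61 and 1.71) and 0.35 for the matrix proteases (0.45 and 0.54). In the neutrophil list it stood at 0.05 (2.01 and 2.35), and in the T cell list at 0.00 (0.45 and 1.05), in both below control replicates 1 (0.78 and 0.35) and 2 (0.15 and 0.67).

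Interferon-induced genes rose as a group and in a different pattern over the libraries. Of 31 tested members 29 rose and 0 fell (31 and 0 over the list alone), including the antiviral gene Ifit1, from 5.60 ± 0.718 to 21.3 ± 1.58 CPM, the deubiquitinase gene Usp18, from 4.36 ± 0.431 to 11.5 ± 0.444 CPM, the tethering factor gene Bst2, 1.71-fold, and Xaf1, 1.90-fold. Camera gave an adjusted p of 4.66e-41 with the preset correlation and 0.213 with an estimated one, and fry, which asks whether the members move 1 way, gave 0.00531. The median log2 rise over the list was 1.37, 1.41 and 1.34 in knockout replicates 1, 2 and 3.

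**Figure D2:**
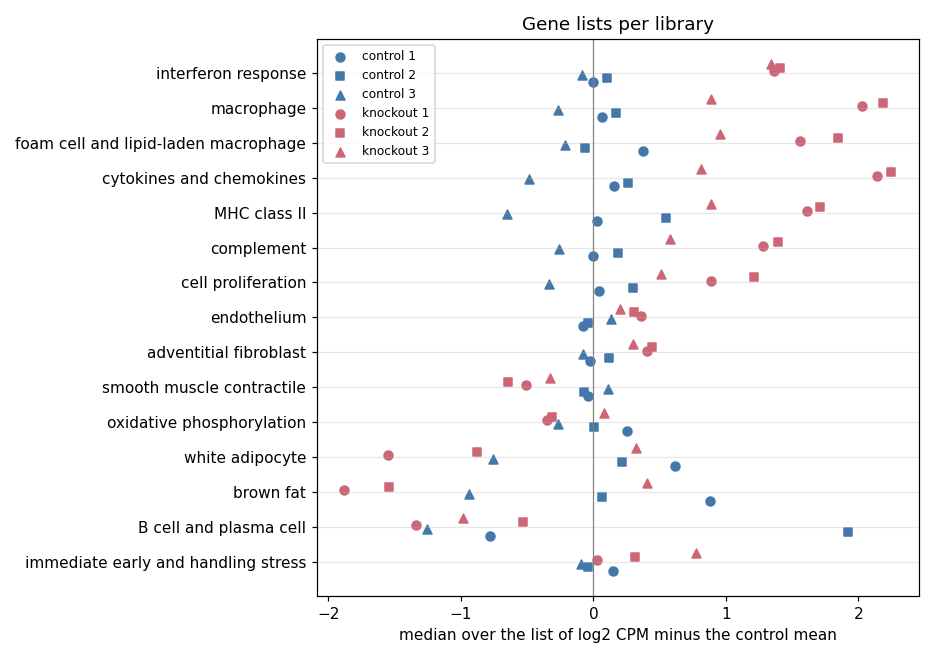
Median over each of 15 gene lists (vertical axis) of log2 CPM minus the control mean (horizontal axis) in each of the 6 libraries, with blue points for controls and red points for knockouts. In the interferon list the 3 knockouts lie together near 1.37, in the macrophage list knockout replicate 3 lies at 0.89, and in the brown fat list the controls spread from -0.94 to 0.88.

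Smooth muscle contractile genes were lower. Of 27 tested, 15 fell and 0 rose (24 and 0 over the list alone), with the actin gene Acta2 falling from 13784 ± 955 to 9256 ± 680 CPM, the calponin gene Cnn1 from 1334 ± 117 to 962 ± 21.4 CPM, and Pdlim3 by 1.71-fold. Camera gave an adjusted p of 4.37e-16, and 0.422 with an estimated correlation. Among genes of modulated smooth muscle and cartilage, 8 of 24 rose and 0 fell (11 and 0 over the list alone), with the adhesion gene Vcam1 at 3.49-fold and the stem cell antigen gene Ly6a at 1.97-fold; the adjusted p was 0.000224, and 0.515 with an estimated correlation. The list's median stood at 0.27 in knockout replicate 3, against 1.15 and 1.22 in the other knockouts and 0.13 in control replicate 2. This list of modulated smooth muscle and cartilage shares Ly6a, Lum and Dcn with the adventitial fibroblast list. It also shares Vcam1 with the leukocyte adhesion list, and Spp1 and Lgals3 with the foam cell list. Its rise is therefore not separate from theirs and does not by itself show a change of smooth muscle cells. The adventitial fibroblast list had 10 of 23 members higher and 1 lower (18 and 1 over the list alone), the proteoglycan gene Lum at 3.42-fold and Fbln1 at 1.47-fold, at an adjusted p of 6.61e-07, and 0.422 with an estimated correlation. In the list of extracellular matrix and collagen 3 of 42 rose and 12 fell (6 and 13 over the list alone), with the collagen genes Col6a3, Col15a1 and Col4a2 lower by 1.69-fold, 1.67-fold and 1.51-fold; camera did not call it (adjusted p = 0.0582), and its median log2 difference was 0.02 where the camera direction was down. Camera did call it without control replicate 3 (adjusted p = 0.0268), without knockout replicate 2 (0.0107) and with the perivascular fat covariate (0.00542), with medians of -0.0032, -0.0518 and 0.00; with an estimated correlation in all 6 libraries the adjusted p was 0.734.

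Of 24 tested endothelial genes, 8 rose and 0 fell (10 and 0 over the list alone), among them the transcription factor gene Sox17, 1.42-fold, and the tight junction gene Cldn5, 2.06-fold, while Pecam1 and Erg, which did not pass, had log2 differences of -0.07 and -0.28. In the lymphatic endothelium list 3 of 9 rose (8 over the list alone), Prox1 at 2.03-fold. Of 30 proliferation genes 7 rose and 0 fell (27 and 1 over the list alone), the kinase gene Cdk1 3.06-fold. Of 26 immediate early genes, which also respond to handling of tissue, 6 rose (7 over the list alone), and Junb and Egr3 stood highest in knockout replicate 3, at 186 and 69.4 CPM. The immediate early list's median stood at 0.03, 0.31 and 0.77 in knockout replicates 1, 2 and 3, so knockout replicate 1 lay below control replicate 1 (0.15). In the proliferation list knockout replicate 3 stood at 0.51, against 0.89 and 1.22 in the other knockouts and 0.30 in control replicate 2. Camera called the endothelial, lymphatic, proliferation and immediate early lists at adjusted p of 0.000194, 7.57e-06, 8.01e-11 and 0.000121, and with an estimated correlation the adjusted p were 0.422, 0.422, 0.471 and 0.448.

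Other lists called lower by camera held few or no called genes. None of 18 brown fat, 20 white adipocyte, 50 oxidative phosphorylation, 19 B and plasma cell, 24 cholesterol synthesis or 21 fatty acid and triglyceride synthesis genes passed, and of 23 fatty acid oxidation genes Eci2 alone passed, as a rise of 1.31-fold; over each list alone the counts were also 0, and 1 for Eci2. Their camera adjusted p were 0.0102, 0.00778, 0.000434, 0.0159, 0.0211, 0.0498 and 0.0164, and with an estimated correlation each was 0.734. Perivascular fat differed within the groups, the brown fat median being 0.88 and -0.94 in control replicates 1 and 3, and -1.88, -1.54 and 0.41 in knockout replicates 1, 2 and 3. With this level as a covariate all 7 lists lost the call, with adjusted p between 0.128 and 0.956. The covariate was built from the genes of the brown fat and white adipocyte lists, so the loss of their calls follows from its construction. The fatty acid lists share members with them, such as Dgat2, Cpt1b and Ppara, so they are not an independent check either. Without control replicate 1 the lists other than B and plasma cells lost it (0.0636 to 0.515), without knockout replicate 1 those other than B and plasma cells and oxidative phosphorylation lost it (0.0627 to 0.363), and without knockout replicate 2 cholesterol synthesis, fatty acid and triglyceride synthesis and fatty acid oxidation lost it (0.0517 to 0.14). With the covariate the oxidative phosphorylation median was 0.00 (adjusted p = 0.944), while the interferon, macrophage and contractile lists had adjusted p of 7.89e-67, 1.83e-13 and 4.08e-19 at the preset correlation; without the covariate and with an estimated correlation these lists had 0.213, 0.422 and 0.422. The B cell list rested on control replicate 2, with a median of 1.92 there and below the control mean in the other controls. Without that library its median log2 difference was 0.08 (adjusted p = 0.592), and without knockout replicate 3 its adjusted p was 0.0961.

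The lists with no camera call had these counts of higher and lower members. For nerve they were 2 and 1 of 16, for Schwann cell 0 and 1 of 15, for skeletal muscle 2 and 0 of 18, for cardiomyocyte 1 and 2 of 13, for thymocyte 0 and 1 of 14, for the airway and oesophagus epithelium 1 and 1 of 6, for the circadian clock 1 and 0 of 18, for TGF-beta and BMP signalling 3 and 1 of 35, and for the NRF2 and antioxidant list 0 and 1 of 22. No member passed among 12 erythroid, 11 platelet, 10 mast cell, 10 mesothelium and 22 unfolded protein response genes. Without control replicate 3 camera called nerve (adjusted p = 0.0302), cardiomyocyte (0.0125), thymocyte (0.0196) and erythroid (0.0335), and without control replicate 1 platelet (0.0498) and mesothelium (0.0176). With an estimated correlation in all 6 libraries, the adjusted p of these 6 lists were between 0.609 and 0.834. Of 45 neighbours of Mir26b on chromosome 1, the metal transporter gene Slc11a1, which macrophages express, rose 3.94-fold and Gmppa fell by 0.26 on the log2 scale. Over the list alone 2 members rose and 7 fell, and the list's camera adjusted p was 0.323.

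Genes with the seed site did not stand apart as a set, which cannot show that direct targets were unaffected. The related miR-26a, whose host genes Ctdsp2 and Ctdspl were still expressed in the knockouts, was not measured. Whether it acts on the same sites was not tested. The 778 tested genes with the 8-base site UACUUGAA in their longest 3′ UTR had a mean log2 difference of 0.07, against 0.09 for 15444 other genes with an annotated 3′ UTR. Camera in limma, run across genes, did not call this comparison at 0.05, and an exact permutation test over the 10 splits of the libraries into 3 and 3 gave p = 0.3 (two-sided, smallest possible 0.1), since 3 of the 10 had a camera result as strong. Of the site genes 5.4% were higher and 4.9% lower, against 6.7% and 3.9% of the others. The site genes have longer 3′ UTRs, with a median of 2795 bases against 1130, and against length-matched genes without a site the difference in means turned from -0.02 to 0.0316. Among 359 shuffled sequences of the same bases, 38 gave a difference in means at least as high as that of the real site, and the shuffled sequences ranged from -0.13 to 0.03, with a median of -0.053. Of 46 tested genes reported as miR-26 targets in the literature, 6 rose and 0 fell (7 and 2 over the list alone), at a camera adjusted p of 0.17, 0.0228 without knockout replicate 3, and 0.734 with an estimated correlation in all 6 libraries. These were Hgf, a growth factor gene (8.77-fold, 2.77 ± 0.665 to 24.3 ± 12.6 CPM), Ptgs2 (3.83-fold), Hmga2 (2.12-fold), Hmga1 (1.79-fold), the cholesterol exporter gene Abca1 (2.48-fold) and the sheddase gene Adam17 (1.24-fold), with adjusted p between 0.0168 and 0.0456. Among all 17392 tested genes, 1131 were higher and 667 lower. Ptgs2 is also in the cytokine list, and Abca1 in the foam cell and LXR lists, so these rises are counted there too. Hgf and Abca1 stood lower in knockout replicate 3 (9.79 and 153 CPM) than in the other knockouts, as macrophage genes did. Whether the 6 genes rose as direct targets was not tested.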

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

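All alternatives were chosen before the data were examined except removal of the scaling constant and summing of copies. The cause of each change below was not tested unless the construction shows it. The counts of 1131 higher and 667 lower genes moved by over 1.5 times as follows. DESeq2 called 2086 and 1357, limma-voom called 559 higher, limma-voom with sample weights 3330 and 2553, limma on log2(TPM + 1) 461 and 251, limma on log2(TPM + 0.1) 641 and 301, and with the perivascular fat covariate, which also takes 1 residual degree of freedom, the calls were 147 and 135. With 1 library left out, the higher genes ranged from 0 (without control replicate 1 and without control replicate 3) to 3051 and the lower genes from 0 to 2028 (without knockout replicate 3). Of the 168 named genes 110 were called, and 0 of these changed direction under any alternative that gave them a value. All 110 lost their call without control replicate 1, and all 110 without control replicate 3. Of the 110, 100 lost it without control replicate 2, 108 without knockout replicate 1, 97 without knockout replicate 2 and 81 with the fat covariate. Calls of named genes were also lost with limma-voom (31), limma on log2(TPM + 1) (40), limma on log2(TPM + 0.1) (22), the replicate block (11, with 7 gained), library size alone (3, with 4 gained) and no low-count filter (2, with 2 gained), and were gained with DESeq2 (24), limma-voom with sample weights (42) and without knockout replicate 3 (38), with none lost in these 3. The counts of 17 lists higher and 8 lower became 0 and 0 with an estimated correlation, and 1 and 0 with fry, which tests a list against no change and not against other genes; the lower lists were 5 with limma-voom and 2 with the fat covariate. With 1 library left out, the lists ranged from 17 to 19 higher and from 3 to 11 lower. Camera calls were gained for T cells with median of ratios (adjusted p = 0.0476), upper quartile (0.0426), no low-count filter (0.0174), the replicate block (0.00152) and without X and Y genes (0.0481), for extracellular matrix and collagen with no low-count filter (0.0288), the fat covariate (0.00542) and without genes of neighbouring tissues (0.0442), for nerve with no low-count filter (0.0288) and for the unfolded protein response with sample weights (0.011). Calls were lost for fatty acid and triglyceride synthesis with median of ratios (0.0532), upper quartile (0.0579), the stricter filter (0.104), limma-voom (0.0637), the replicate block (0.067) and without genes of neighbouring tissues (0.0623), for B and plasma cells with the stricter filter (0.148), limma-voom (0.0867) and sample weights (0.0523), and for cholesterol synthesis with limma-voom (0.0502).

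The seed site difference in means was -0.02, between -0.0446 and -0.011 with 1 library left out, 0.0316 against length-matched genes without a site, -0.0546 for genes with an 8-base or 7-base site and -0.0748 for genes with 2 or more sites, and its p lay between 0.0954 and 0.705 over the alternatives. With the replicate number as a block, edgeR called 1295 higher and 700 lower genes, 18 lists were higher and 7 lower, and the seed difference was -0.0194. Correlations of deviations were -0.09, 0.23 and 0.08 for equal numbers, and between -0.206 and 0.116 for unequal ones. The highest, 0.23, was thus of an equal pair, while control replicate 1 correlated best with knockout replicate 3 (0.072). So few correlations cannot show whether equal numbers mark pairs.

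Lists whose median or camera direction turned belonged mostly to those with no call, and the values are their medians. With library size alone these were neighbours of Mir26b at 0.0061 and mast cell at -0.0422. With the stricter filter they were thymocyte at 0.1301, extracellular matrix and collagen at -0.0049 and cardiomyocyte at 0.3555. With limma-voom it was NRF2 and antioxidant at -0.051, and with sample weights mast cell at -0.3612 and skeletal muscle at 0.0134. With log2(TPM + 1) they were neighbours at 0.004, collagen at -0.004, NRF2 at -0.0306 and the gene Ctdsp1 at 0.007365; with log2(TPM + 0.1) they were neighbours at 0.004, mast cell at -0.0905, collagen at -0.0044, NRF2 at -0.0317 and Ctdsp1 at 0.007422. With the fat covariate, thymocyte stood at 0.1444, mast cell at 0.178, white adipocyte at 0.0174, fatty acid and triglyceride synthesis at 0.1181, fatty acid oxidation at 0.0199, oxidative phosphorylation at 0.0036, circadian clock at 0.0252 and NRF2 at 0.0707. With 1 library left out the ranges were -5.319 to 0.1289 for Igkc, -2.2931 to 0.0833 for B and plasma cells, -0.0982 to 0.0333 for NRF2, 0.0849 to 0.2281 for Schwann cell, -0.1356 to 0.0402 for circadian clock, -0.3445 to 0.4064 for epithelium, -0.6954 to 0.0315 for erythroid, -0.0518 to 0.0561 for collagen, -0.2664 to 0.1067 for mast cell, -0.1548 to -0.003 for skeletal muscle and -0.3208 to 0.0809 for thymocyte. Igkc and the B cell list turned only without control replicate 2.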

Other observations

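The tests in this part were chosen after the results they bear on were seen, except the camera test of the neighbours of Mir26b. Some genes separated the groups while knockout replicate 3 stood with the other knockouts. They were chosen after their values were seen, as called genes with at least a 2-fold difference and a log2 position of knockout replicate 3 between 0.8 and 1.25, where 0 is the control mean and 1 the mean of the other knockouts. There were 83, 62 higher and 21 lower, of which 14 belong to the interferon list and 66 to no gene list. Further interferon-related genes among them were Rtp4 (2.97-fold higher), Phf11b (3.06-fold), Ifi206 (4.94-fold) and Ddx60 (2.22-fold). Both rows of Nnt, the mitochondrial transhydrogenase gene on chromosome 13 (119335448 to 119408997), were higher in the knockouts, by 2.08 (SE 0.21) and 0.85 (SE 0.09) on the log2 scale, from 12 ± 3.4 to 50.7 ± 4.51 CPM and from 19.7 ± 2.33 to 35.4 ± 0.769 CPM (n = 3). Gm10184 stood at 0.0444 CPM in controls and 20.3 CPM in knockouts, and Gm13301 at 10.2 and 0.927 CPM.

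Knockout replicate 3 lay between the groups for macrophage genes, with a median linear position of 0.26 over that list (quartiles 0.23 and 0.30). RNA of a control animal mixed in would bring every gene to about the same position, and the tables argue against it, since the interferon list had a median of 0.8 (quartiles 0.67 and 0.94). This library held more fat RNA than the other knockouts, with median log2 differences from them of 2.09 over the brown fat list and 1.52 over the white adipocyte list. Dilution by that fat would lower contractile and macrophage genes alike, and as the whole cause it is argued against by a median difference of 0.28 over the contractile list (lower quartile 0.13), against -1.14 over the macrophage list. A smaller plaque in the dissected segment stays open and was not tested, since the labels give no lesion size.

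Some of these differences may reflect genome of another mouse strain carried with the knockout allele. Within 20 Mb of Mir26b lay 5 of the 83 genes, but the window was chosen after 2 of them, Neu2 and Ugt1a6b, had been seen. Without these 2 it held 3 of 280 tested genes, against 78 of 17110 elsewhere (odds ratio 2.36, Fisher's exact p = 0.142, two-sided). This window covers chromosome 1 alone. The 78 genes elsewhere include Nnt on chromosome 13, Gm10184 on chromosome 17 and Zfp264 on chromosome 7, and a strain difference at such places was not tested. The list of neighbours fixed beforehand was not called by camera (adjusted p = 0.323), which looks for a shift in 1 direction and so cannot decide this. Over the list alone 2 members rose and 7 fell. The mixed test of fry, open to both directions but made against no change and not against other genes, gave an adjusted p of 0.0359. That test gave 0.0101 for the skeletal muscle and Schwann cell lists too, and 0.433 and 0.528 for the erythroid and mast cell lists. It therefore does not single out the neighbours and cannot decide this either. The labels do not give the strain background, so genotype and strain cannot be told apart here. Of the 83 genes, 1 (1.2%) shared its symbol with another entry of the table or lay off the chromosomes. Reads shared between relatives with other names, as among the genes near 42 Mb of chromosome 4, were not tested.

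Interferon genes stood near their full level in knockout replicate 3 while macrophage genes did not, a difference in median log2 position of 0.42 (0.87 with quartiles 0.77 and 0.95, against 0.45 with quartiles 0.43 and 0.49). A larger macrophage share alone would give both lists the same position on the linear scale, and not on the log2 scale. The linear medians were 0.8 (quartiles 0.67 and 0.94) for interferon and 0.26 (0.23 and 0.30) for macrophage genes, which argues against it as the whole cause. Loss of Mir26b and a strain background remain candidate explanations that these libraries do not separate.

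The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. In 1 of the 10 splits, the real one, edgeR called 1798 genes, and the highest count in another split was 0. For gene lists 3 of the 10 splits called as many as the real 25, and the other counts ranged from 13 to 26. For the seed sites 3 of the 10 gave a p as low as 0.339, the lowest other being 0.126.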
